A study of Mus musculus with 11 samples.

How the data were processed

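GATA3 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse pro-T cells grown from bone marrow progenitors. Per the labels, the series held 11 samples. The ChIP samples were 2 of DN1 cells and 2 of DN3 cells fixed with DSG and formaldehyde, and 2 of DN3 cells fixed with formaldehyde alone. The input samples, chromatin sequenced without precipitation, were 2 of DN1 and 2 of DN3 under the double fixation and 1 of DN3 under formaldehyde. Per the labels' protocols, DSG was applied at 1 mg/ml for 30 min and formaldehyde at 1% for 10 min. Each precipitation used 5 ug of antibody, a mixture of 2 monoclonal antibodies of 2.5 ug each, and reads of 50 nt were sequenced from a single end. Nothing in the labels stated that replicates came from separate animals or cultures.

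The values used were 3 deposited peak lists, 1 per ChIP group. Bowtie 1.1.1 and HOMER were named in the submitters' processing notes, which also named the genome builds mm9 and mm10 without a role. Per the file headers, each list was annotated with HOMER's annotatePeaks against mm10, and all coordinates given here are mm10. Per the file headers, the DN1 list and the DN3 list of the double fixation were each made from 2 libraries with IDR, a method that keeps peaks ranked alike in both replicates. The header of the formaldehyde list named 1 library and no IDR, and how its 2 labelled replicates entered the list was not given in the sources used here. Each header name ended in the number 15. The peak score in the deposited lists was the authors', its unit was not stated, and its lowest value was 15.1 in DN1 and 15.0 in both DN3 lists. Scores were used only to rank, filter or describe peaks within their own list. The focus ratio, a fraction between 0 and 1 that the authors deposited per peak, entered no comparison. The authors' lists also gave the nearest transcription start site (TSS), the signed distance to it, a genomic annotation and a repeat annotation. All peaks of a list had the same span between start and end, 250 bp in DN1, 270 bp in DN3 and 404 bp in the formaldehyde list.

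No read counts or values per replicate were analysed here, so sequencing depth was unknown and no difference between stages could be set against the spread between replicates. Tests over peaks or genes compare the deposited lists, and their p-values say nothing about variation between cultures. Wilson 95% intervals cover counting error over peaks alone. The planned edgeR test per replicate was not run because the lists held no counts. The planned motif comparison was not run because no genome sequence was used here.

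Peaks were called shared where they overlapped by at least 1 bp. With fixed spans this rule set a limit on the distance between peak centres of 260.5 bp for DN1 and DN3 and of 337.5 bp for the DN3 lists. Chance overlap was taken from 100 shuffles of the peaks within their chromosomes. DN1-only and DN3-only peaks were those with no overlapping peak in the other list of the double fixation. Shared peaks were described by their DN3 member. Promoter peaks were those annotated so in the authors' lists, which lay at most 1000 bp from a TSS. Not every peak that close was annotated so. A DN3 peak at 135 bp from the Psmc3 TSS counted as 5' UTR, and a DN1 peak at 950 bp from the Hhex TSS as intron. Shares were compared with Fisher's exact test over peaks, two-sided, in a family of 9 tests, and are given as odds ratios with 95% intervals because most p-values were too small for the number format. Median scores were compared with a two-sided permutation test of 100000 resamples, and of 10000 resamples under the alternatives.

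Each peak counted for the gene the authors' list named for it, which was given for 92.4% of DN1, 92.0% of DN3 and 91.9% of formaldehyde peaks. In total 13 gene lists with 244 genes were fixed before the data were examined, and all 244 were found in the RefSeq gene table of assembly GRCm38.p6, the build called mm10, from which gene coordinates were taken. A peak was assigned to 223 of these genes. For each gene list the DN3-only share of its stage-specific peaks was compared with 10000 random gene lists of the same size matched on peaks per gene, as a two-sided permutation test with Benjamini-Hochberg adjustment over the 13 lists. The same test compared the DN3 lists of both fixations. That use, and an exact binomial test per gene against the share over all genes, were added after the data were seen.

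Genes were named by a rule fixed at the same time as the lists. It took Spi1 and Bcl11a, the 10 listed genes with the largest excess of DN3-only peaks and the 10 with the largest excess of DN1-only peaks, with ties going to genes with more peaks. It also took the genes of the 3 highest-scored peaks of each class, the 10 listed genes that differed most between fixations, and examples per gene list in the order of their number of peaks. Other genes are marked as chosen after their values were seen.

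The procedures were tested on simulated data. Planted overlaps of 19.6%, 49.7% and 80.0% of the 29236 DN1 peaks were found as 20.0%, 49.8% and 80.1%. Planted partners lay within 100 bp, inside the limit for sharing, so their recovery was given in advance. Of 200 random gene lists of 20 genes without bias, 5.5% were called at an unadjusted p under 0.05. Of 50 such lists with a planted DN3-only share of 80%, 80% were called, and with a planted share of 35%, 100% were called. These simulations drew the peaks of a gene independently, so the rates may differ where peaks of a gene go together. The alternatives were other overlap rules (50% of both spans, centres within 100 bp, gaps of up to 500 bp), higher score thresholds, lists of equal length, chromosomes 1 to 19, other promoter limits, peaks within 50 kb of a TSS, genes counted a single time, and peaks outside promoters. For higher score thresholds and equal lengths, the lists compared were cut before overlaps were called. A peak whose partner was cut then counted as found in 1 list alone. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.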

Results

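GATA3, a zinc finger transcription factor required for T cell development, was mapped across the genome of mouse pro-T cells by ChIP-seq. Bone marrow progenitors of C57BL6/J mice were grown on OP9-DLL1 stroma, a feeder layer that presents a Notch ligand, with IL-7 and Flt3L. Cells were compared as DN1, the stage before T-lineage commitment, and DN3, the stage after it. The series title concerns the roles of Runx1 and GATA3 in silencing PU.1, the product of Spi1. DN1 and DN3 cells were fixed with DSG, a crosslinker that joins proteins to each other, followed by formaldehyde, and DN3 cells also with formaldehyde alone. Each of these 3 groups had 2 ChIP samples, and the 5 remaining samples were inputs. The deposited lists held 29236 GATA3 peaks in DN1, 36479 in DN3 and 36288 in DN3 cells fixed with formaldehyde alone. There was 1 list per group with no values per replicate, so the depth behind a peak was unknown and no value below carries a replicate error.

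The comparison of DN1 with DN3 asked how GATA3 occupancy differed between these stages. Promoter peaks recurred between the stage lists far more often than peaks outside promoters. Of the DN1 peaks at promoters, 91.6% overlapped a DN3 peak, against 58.2% of those outside promoters. Of the DN3 promoter peaks, 84.3% overlapped a DN1 peak, against 44.4% outside promoters. Over all peaks, 19657 of the 29236 DN1 peaks were shared, or 67.2% (95% Wilson interval 66.7 to 67.8), which left 9579 DN1-only peaks. In DN3 the shared part was 53.9% (53.4 to 54.4), which left 16822 DN3-only peaks. Shuffled peaks overlapped at 0.778% for DN1 and 0.624% for DN3.

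High-scored peaks recurred most. With each list divided by score into 4 equal parts, 85.0% of the highest-scored DN1 part were found in DN3, against 49.2% of the lowest-scored part. The corresponding shares of the DN3 list were 81.3% and 24.8%. The median score of DN1 peaks was 31.9 where shared and 22.1 where DN1-only, and that of DN3 peaks was 41.8 where shared and 22.8 where DN3-only. Both differences reached p = 1.0e-05 in a permutation test, the smallest value that 100000 resamples can give. Because weak peaks recur less, a peak found in 1 list alone is not by itself shown to be absent from the other stage. Intervals over peaks cover the counting error of the lists, and p-values over peaks compare lists, not conditions, while the ChIP replicates behind a list may be technical.

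**Figure D1:**
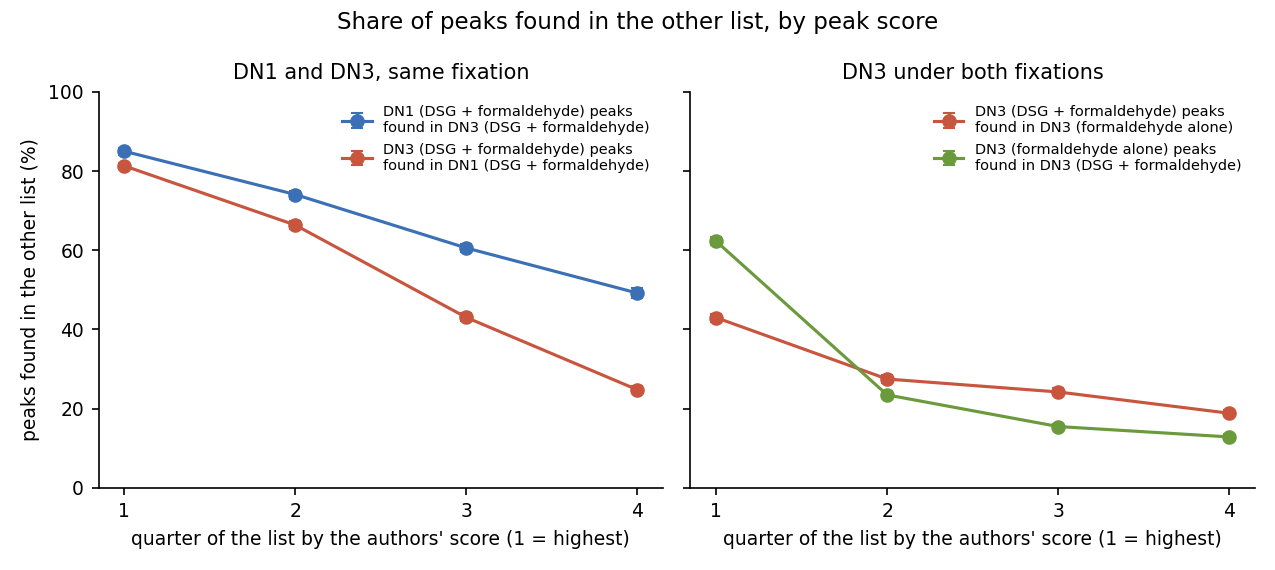
Share of peaks found in the other list (percent, vertical axis) by part of the list, divided into 4 by the authors' score (horizontal axis, 1 is the highest), with Wilson 95% intervals as bars that are mostly smaller than the points. The left panel compares DN1 with DN3 and the right panel the DN3 lists of both fixations; shares run from 85.0% down to 49.2% for DN1 peaks in DN3 and from 62.3% to 12.9% for formaldehyde peaks in the double-fixed DN3 list.

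Stage-specific GATA3 sites lay mostly in introns and between genes. Promoters made up 37.1% of the shared peaks (95% Wilson interval 36.5 to 37.8), 6.98% of the DN1-only peaks (6.49 to 7.51) and 8.10% of the DN3-only peaks (7.69 to 8.52). The median distance to a TSS was 4.85 kb for shared peaks, 18.1 kb for DN1-only peaks and 20.5 kb for DN3-only peaks. Shared peaks exceeded DN1-only peaks in promoter content with an odds ratio of 7.87 (95% interval 7.23 to 8.55) and DN3-only peaks with an odds ratio of 6.70 (6.30 to 7.14). The smaller difference between DN3-only and DN1-only peaks, 1.11 percentage points, had Fisher's exact p = 0.00109 over peaks (two-sided). It was not called where sharing required an overlap of 50% of both spans (0.07 points) or where promoters reached 2500 bp from a TSS (0.42). It was 2.03 points with gaps of up to 500 bp and 10.3 in the higher-scored of 2 equal parts of each list. In that last setting both lists were cut before overlaps were called. Peaks whose partner had a lower score counted there as stage-specific, so 10.3 does not describe the classes as defined above.

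The list from DN3 cells fixed with formaldehyde alone gave a further look at these classes. It contained 5252 of the 16822 DN3-only peaks (31.2%, 95% Wilson interval 30.5 to 31.9), 5104 of the 19657 shared peaks (25.4% to 26.6%) and 766 of the 9579 DN1-only peaks (7.47% to 8.56%). DN3-only sites thus recurred in the other DN3 list more often than DN1-only sites, with an odds ratio of 5.22 (95% interval 4.82 to 5.66). Outside promoters the shares were 32.8% for DN3-only, 34.9% for shared and 8.19% for DN1-only peaks. Fisher's exact test here compares lists of peaks and not replicate cultures.

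Stage-specific GATA3 sites near genes of T-lineage commitment and identity belonged mostly to DN3, and those near progenitor genes mostly to DN1. The T-lineage list, which covers transcription factors, T cell receptor signalling components and recombination genes, carried 115 DN3-only peaks, 29 DN1-only peaks and 69 shared peaks over 30 genes, among them Themis, Prkcq and Tox. DN3-only peaks were 79.9% of its stage-specific peaks, against a median of 63.8% in matched random gene lists (two-sided permutation p = 0.002, adjusted 0.013). In 23 of the 30 genes DN3-only peaks were in excess, in 3 DN1-only peaks, and 4 were even. The list of progenitor and phase 1 regulators, genes active in stem and progenitor cells and in the earliest pro-T cells, carried 18 DN3-only peaks, 37 DN1-only peaks and 43 shared peaks over 18 genes, among them Erg, Mef2c and Kit. DN3-only peaks were 32.7% of its stage-specific peaks, against a random median of 63.1% (permutation p = 0.0004, adjusted 0.0052). DN1-only peaks were in excess in 12 of these 18 genes and DN3-only peaks in 2. With each gene counted a single time the T-lineage result no longer passed, at 88.5% against a random median of 70.8% (adjusted permutation p = 0.219), while the progenitor result did, at 14.3% against 69.2% (0.0026). With lists of equal length, cut before overlaps were called, the progenitor share was 21.4% against a random median of 50.0%. In the formaldehyde DN3 list, 48 of the 115 DN3-only peaks near T-lineage genes were found again (41.7%) and 7 of the 18 near progenitor genes (38.9%). Of the DN1-only peaks it held 1 of 29 near T-lineage genes (3.45%) and 1 of 37 near progenitor genes (2.70%), so in both lists the contrast followed the class of the peaks.

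Among T-lineage genes the largest excesses of DN3-only peaks belonged to Themis and Thy1. Themis, a regulator of T cell receptor signalling, had 12 DN3-only and 3 DN1-only peaks. The highest-scored DN3-only peak assigned to it lay at -154585 bp from its TSS, in an intron of another transcript. Thy1, which encodes a surface marker of T cells, had 9 DN3-only and 0 DN1-only peaks. Lef1, which encodes a transcription factor of the Wnt pathway, Rag2, which encodes part of the V(D)J recombinase, and Bcl11b, which encodes a factor that secures T-lineage commitment, each had 7 DN3-only and 0 DN1-only peaks. No DN1 peak at all was assigned to Bcl11b. Its highest-scored DN3 peak was at the promoter (chromosome 12, 108003981 to 108004251, score 44.7). The highest-scored DN3-only peak of Rag2 lay between genes on chromosome 2 (101551441 to 101551711, score 227.0), at -73172 bp from the TSS, and was also present under formaldehyde alone. That of Thy1 lay at -21129 bp on chromosome 9 (44022120 to 44022390, score 103.5). The highest-scored DN3-only peaks of Themis, Thy1, Lef1 and Bcl11b were not found under formaldehyde alone. Of the 7 Bcl11b peaks, 0 were found there, while the formaldehyde list held 4 other peaks assigned to Bcl11b. Formaldehyde peaks that overlapped double-fixed DN3 peaks numbered 8 at Themis, 4 at Thy1 and 5 at Lef1.

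Gata3 itself was 1 of the 3 T-lineage genes with an excess of DN1-only peaks, with 3 DN1-only peaks and 0 DN3-only or shared peaks. The highest-scored of them lay between genes on chromosome 2 (9688270 to 9688520, score 88.9), 190205 bp downstream of its TSS. These counts rest on assignment to the nearest TSS. The whole stretch from Gata3 to the next protein-coding gene on that side, chosen after its values were seen, leaned the other way. It held 2 DN1-only, 8 shared and 19 DN3-only peaks. Among progenitor genes, Flt3, a cytokine receptor of early progenitors, had 4 DN1-only and 0 DN3-only peaks, the highest-scored in intron 1 (chromosome 5, 147392818 to 147393068, score 46.1). Hhex, which encodes a homeobox factor, had 3 and 0, with a DN1-only peak of score 190.2 in intron 1 (chromosome 19, 37435666 to 37435916). Erg, the progenitor gene with the most peaks, had 6 DN1-only, 5 shared and 4 DN3-only peaks, and Mef2c had 2, 6 and 1.

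Genes of other lists were also among the listed genes with the largest differences in peak number. These excesses are counted against an even split and not against the share over all genes, to which S1pr1 and Jak1 were close. Tcf12, which encodes the E protein HEB, had 13 DN3-only and 0 DN1-only peaks, the highest-scored in intron 3 (chromosome 9, 72098086 to 72098356, score 130.8). DN3-only peaks were in excess at Socs1, an inhibitor of cytokine signalling (10 against 1), Klf4 (7 against 1) and Jak1 (8 against 3). S1pr1, the receptor that guides thymocyte exit, also had more of them (13 against 5). Peaks were assigned to the nearest TSS, which can be distant. The highest-scored DN3-only peak of Socs1 lay 116873 bp from its TSS, in an intron of another transcript, and that of Klf4 at -204443 bp. DN1-only peaks were in excess at Socs3 (5 against 1), Cebpa, a myeloid regulator (4 against 0), Csf2ra (4 against 1), Zbtb16, the regulator of innate-like lymphocytes (3 against 0), Stat5b (3 against 0), Il6ra (3 against 0) and Runx3 (7 against 5). Tested singly, none of these genes stood apart. In an exact binomial test against the genome-wide DN3-only share of 63.5%, 0 of 10243 genes passed an adjusted p of 0.05 and 237 had an unadjusted p under 0.05. Of the 182 listed genes with a stage-specific peak, 0 passed when adjusted over the list alone and 10 had an unadjusted p under 0.05.

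The other 11 gene lists did not pass the test against matched random lists, with adjusted permutation p between 0.625 and 0.924. DN3-only peaks were 67.2% of the stage-specific peaks for Notch pathway genes such as Rbpj and Maml3, 58.9% for GATA3 partner factors such as Runx1, 58.2% for cytokine receptor and signalling genes such as Socs1, 59.5% for later thymocyte genes such as S1pr1 and 65.5% for B cell genes such as Bach2. They were 54.1% for myeloid and dendritic genes such as Ly86, 48.1% for erythroid, megakaryocyte and mast cell genes such as Itgb3, 52.9% for NK and innate lymphoid genes such as Rora and 55.6% for Th2 effector genes such as Maf. The erythroid, megakaryocyte and mast cell share was 29.2% against a random median of 60.9% in the higher-scored of 2 parts of each list (permutation p = 0.0154, adjusted 0.0667) and 28.0% against 50.0% with lists of equal length (0.0534, adjusted 0.218). The myeloid and dendritic share was 35.2% against 50.0% with lists of equal length (permutation p = 0.084, adjusted 0.218), and the stromal share 33.3% in the higher-scored part (0.474, adjusted 0.685). In that part the B cell share went the other way, at 90.0% against 61.5% (permutation p = 0.0494, adjusted 0.161). In these settings the peak lists were cut before overlaps were called, for the random gene lists as well. Runx1, the factor named with GATA3 in the series title, had 10 DN1-only, 13 shared and 11 DN3-only peaks. Genes of the stromal feeder such as Cxcl12 had 5 DN1-only and 11 DN3-only peaks, and housekeeping genes such as Ywhaz also had 5 and 11, or 68.8% in both lists.

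**Figure D2:**
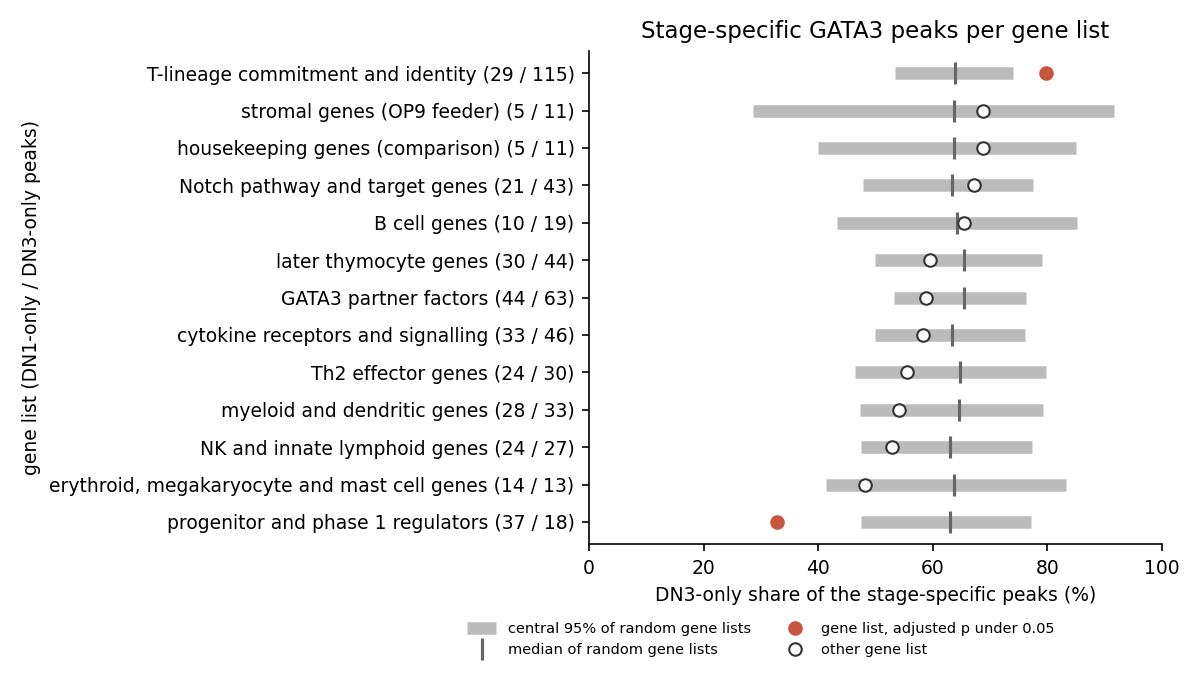
DN3-only share of the stage-specific GATA3 peaks (percent, horizontal axis) for each of the 13 gene lists (vertical axis, with DN1-only and DN3-only peak numbers in brackets). Points are the lists, filled where the adjusted p was under 0.05; grey bars span the central 95% of 10000 matched random lists and ticks mark their medians. The T-lineage list at 79.9% lies above its bar and the progenitor list at 32.7% below it.

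At Spi1, which encodes PU.1, GATA3 had a promoter peak in the DN1 list and none in the DN3 list of the same fixation. The promoter peak (chromosome 2, 91096555 to 91096805, score 41.6) lay 2 bp from the TSS. A peak in intron 2 was shared, with a score of 23.0 in DN1 (91101498 to 91101748) and of 15.2 in DN3 (91101453 to 91101723), where it ranked 36113 of 36479 peaks. A further shared peak, which the lists assign to the neighbouring Slc39a13, lay at -13.6 kb from the Spi1 TSS (91082957 to 91083207, score 65.7 in DN1 and 32.3 in DN3), in the part of the locus where a distal enhancer of Spi1 is known. Scores of different lists are not on a shared scale. Under formaldehyde alone the list held 2 peaks within 50 kb of the gene span, at -63.5 kb and 48.5 kb from the TSS, and none of them overlapped a peak of the other lists. The missing promoter peak there says little, since that list held 11.2% of the double-fixed DN3 promoter peaks and also lacked the shared peaks at the TSS of Slc39a13 and of Psmc3 at this locus.

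Bcl11a, which encodes a zinc finger factor of early progenitors and B cells, had 5 DN1 peaks, 3 DN3 peaks and 5 peaks under formaldehyde alone. All 3 DN3 peaks were shared with DN1. The remaining DN1 peaks, on chromosome 11 at 24184969 to 24185219 (score 25.1) and 24243007 to 24243257 (score 35.5), lay downstream of the gene in intergenic sequence and were DN1-only. The shared peak in intron 2 had a score of 23.2 in DN1 (24131918 to 24132168) and 43.2 in DN3 (24131934 to 24132204). The peak at -28.7 kb from the TSS (24049243 to 24049513 in DN3) was present in all 3 lists. These are single peaks with no test.

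**Figure D3:**
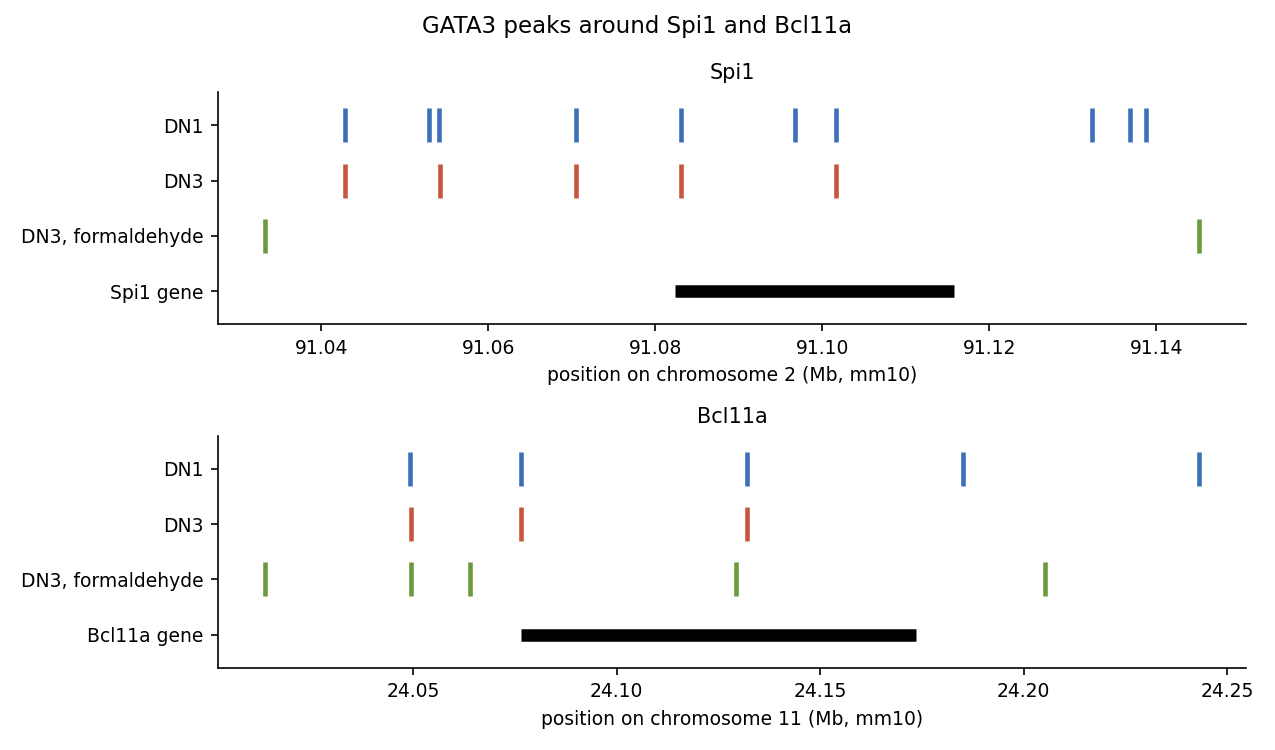
GATA3 peaks around Spi1 (top, chromosome 2) and Bcl11a (bottom, chromosome 11), with position in Mb of build mm10 on the horizontal axis and 1 row per list on the vertical axis. Each tick is the centre of a peak and the black bar is the gene span in the RefSeq table; the Spi1 promoter peak at 91096555 to 91096805 has a tick in the DN1 row alone.

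The highest-scored peaks of the classes lay mostly away from the listed genes. The top shared peaks were intergenic or at a transcript end near G530011O06Rik on chromosome X (169998071 to 169998341, score 4106.4, and 169991228 to 169991498, score 2987.1) and near Erdr1 on chromosome Y (90772407 to 90772677, score 4106.4), and none was in the formaldehyde list. Whether the peaks of equal score on chromosomes X and Y are separate sites was not examined. The top DN1-only peaks were on chromosome Y near 1700020D14Rik (142944 to 143194, score 650.1) and Gm29089 (259162 to 259412, score 585.6, and 261100 to 261350, score 577.5). The first of these lay in a simple repeat. Chromosome Y held 9 of the 100 highest-scored DN1 peaks, against 3 in double-fixed DN3 and 0 under formaldehyde. In all it held 37 DN1 and 31 double-fixed DN3 peaks. The cause was not tested, so these peaks alone do not show binding particular to DN1. The top DN3-only peaks were near Gm20740 on chromosome 15 (63255720 to 63255990, score 376.2), in Gm27162 on chromosome 9 (32928640 to 32928910, score 260.3) and near Mir6947 on chromosome 14 (29997348 to 29997618, score 236.8), and all 3 were found under formaldehyde alone.

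DN3 cells were mapped under both fixations, which asked how far the GATA3 map depended on the crosslinker. Promoters made up 23.7% of the double-fixed DN3 list (8661 peaks) and 4.31% of the formaldehyde list (1565 peaks), while introns made up 36.4% and 44.4% and intergenic sequence 34.4% and 47.5%. The odds ratio for promoters was 6.91 (95% interval 6.53 to 7.31), and the share under formaldehyde minus that under double fixation was -19.4 percentage points, -30.3 in the higher-scored of 2 parts of each list and -32.7 in the highest of 4. Of the double-fixed promoter peaks 11.2% were found under formaldehyde alone, against 33.7% of those outside promoters. Conversely, 59.0% of the formaldehyde promoter peaks were found in the double-fixed list.

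**Figure D4:**
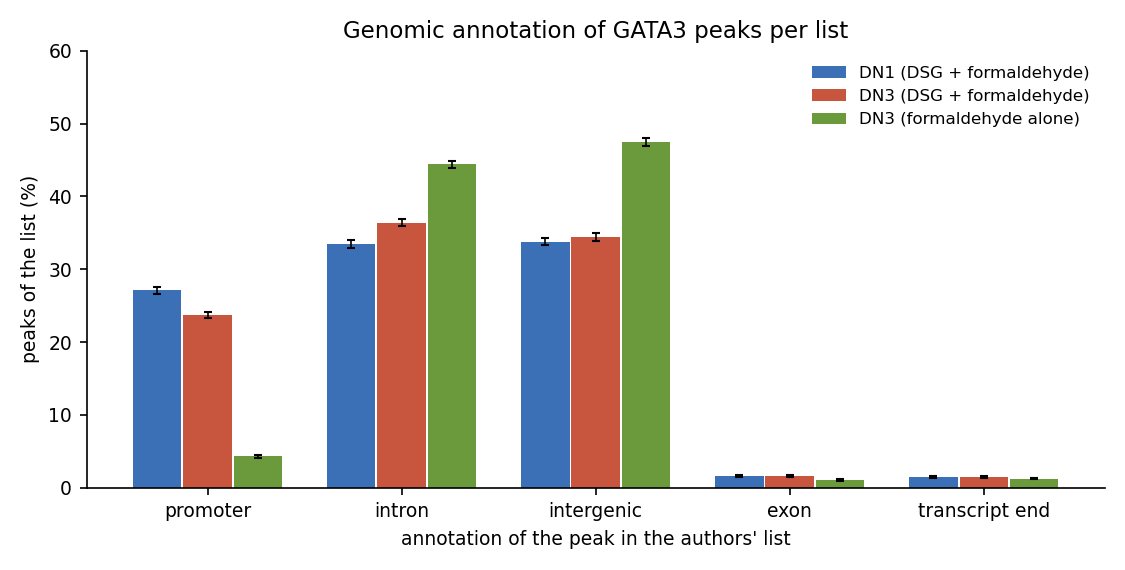
Share of the peaks of each list (percent, vertical axis) by the annotation in the authors' lists (horizontal axis), with Wilson 95% intervals as error bars. Promoters make up 27.1% of the DN1 list, 23.7% of the double-fixed DN3 list and 4.31% of the formaldehyde DN3 list.

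In all, 28.4% of the double-fixed DN3 peaks (10356 of 36479) overlapped a formaldehyde peak and 28.5% of the formaldehyde peaks (10355 of 36288) a double-fixed peak, against 0.961% and 0.963% for shuffled peaks. The strongest formaldehyde sites were nearly all in the double-fixed list. Of the top 1% of formaldehyde peaks 98.3% (356 of 362) were found there, against 62.3% in the highest-scored of 4 parts and 12.9% in the lowest. The median formaldehyde score was 62.3 for shared and 24.8 for other peaks, and the median double-fixed score was 38.9 and 28.6, both with p = 1.0e-05 in a permutation test, the smallest it can give. Fixation cannot be separated here from the way the lists were made. The headers named 2 libraries with IDR for the double-fixed list and 1 library without IDR for the formaldehyde list.

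Peaks near cytokine receptor and signalling genes belonged mostly to double fixation. Jak1 had 6 peaks under double fixation alone and 7 under formaldehyde alone, Socs1 11 and 3, and Il6st 7 and 1. The list had 63 peaks found under double fixation alone, 28 under formaldehyde alone and 28 shared, so that formaldehyde-only peaks were 30.8% of the fixation-specific peaks against a random median of 51.5%. The permutation p was 0.0002, the smallest these random lists can give, and 0.0026 after adjustment, with 14 of 20 genes leaning to double fixation and 5 to formaldehyde. With peaks within 50 kb of a TSS alone the list no longer passed, at 30.7% against a random median of 43.8% (adjusted permutation p = 0.148). The other 12 lists did not pass (adjusted permutation p 0.052 to 0.955). NK and innate lymphoid genes had 33.3% formaldehyde-only peaks (adjusted permutation p = 0.052), housekeeping genes 29.5%, Notch pathway genes 44.9%, myeloid and dendritic genes also 44.9%, B cell genes 46.3%, Th2 effector genes 48.4% and later thymocyte genes 48.6%. The share was 51.2% for GATA3 partner factors, 54.0% for erythroid, megakaryocyte and mast cell genes, 54.3% for T-lineage genes, 56.2% for progenitor genes and 64.5% for stromal genes.

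Tox, which encodes a nuclear factor of T cell development, had 4 peaks under double fixation alone, 6 shared and 23 under formaldehyde alone. It was the 1 gene of 204 listed that passed when adjusted over the list alone (exact binomial p = 0.0345), and it did not pass over all 16120 genes (0.248, exact binomial test). Formaldehyde-only peaks were also more numerous at Maf (26 against 17), Rag2 (15 against 6), Themis (13 against 6), Tcf12 (14 against 8) and Klf4 (16 against 10). Double-fixation peaks were more numerous at Ly86 (18 against 9), Socs1 (11 against 3), Klrb1c (9 against 1) and S1pr1 (13 against 7). None of these 9 genes passed. Over all genes 5 passed and 298 had an unadjusted p under 0.05 in the exact binomial test against a genome-wide formaldehyde-only share of 49.8%. These 5 were named after their values were seen. They were Vwc2 (29 formaldehyde-only against 1), 1700061F12Rik (38 against 5), Lrrc4c (21 against 1), Gm16367 (18 against 0) and Gm16513 (17 against 0). The binomial test takes the peaks of a gene as independent, so genes, Tox included, may pass too easily. Its expected share also counts promoter peaks, which were 4.31% of the formaldehyde list and 23.7% of the double-fixed list. Genes with mostly distal peaks may therefore lean to formaldehyde.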

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

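Of the tests in this part, those of the promoter shares, of the promoter content of the classes and of the LINE shares outside promoters were chosen only after the result was seen. In the DN3 list from formaldehyde alone, 4575 peaks lay in LINE elements (12.6%), 3949 in LTR elements (10.9%), 3047 in SINE elements (8.40%) and 1122 in simple repeats (3.09%). The double-fixed DN3 list held 2.75%, 5.91%, 3.45% and 0.425% in these classes. These values drew attention because the repeat annotation entered no comparison of the report. Among the 100 highest-scored peaks, 23 in DN1 and 30 in DN3 had exactly the score of another peak. Simulated lists held at most 16 and 18. The same score of 4106.4 belonged to DN3 peaks near G530011O06Rik on chromosome X and Erdr1 on chromosome Y. Whether peaks of equal score are separate sites was not examined.

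GATA3 peaks at promoters were 23.7% of the double-fixed DN3 list and 4.31% of the formaldehyde list. Weak peaks near the score threshold are argued against, since among the highest-scored of 4 parts the shares were 38.1% and 5.40%, a difference of 32.73 percentage points. IDR was named for the double-fixed list alone, and it removes peaks and adds none. That list held 8661 promoter peaks, against 1565 in a formaldehyde list of similar length. These numbers cannot decide on IDR selection, since the calls it started from and their depth are not given. The parts of IDR selection, the number of libraries behind each list and the crosslinker in the difference cannot be told apart. The promoter share of the formaldehyde peaks that recurred in the double-fixed list, 8.91%, decides nothing, since all 1565 promoter peaks of the formaldehyde list among these 10355 peaks would still have left the share far below 23.7%. Depth also remains open, because the lists give no counts.

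DN1-only GATA3 peaks were rare in the formaldehyde DN3 list, at 766 of 9579, while 31.2% of the DN3-only peaks were found there. Lower strength of the DN1-only peaks is argued against, since in the highest-scored of 4 parts 61.6% of 1702 DN3-only and 14.6% of 1094 DN1-only peaks were found again, a difference of 46.95 percentage points. A place just below the threshold of the DN3 list predicts recurrence at least as high as in the lowest-scored part of that list. Of that part 18.85% was found again, more than of the DN1-only peaks. The test cannot exclude this explanation, since it compares with peaks that passed the threshold. The share found again fell with score, to 17.8% in the lowest-scored of 10 parts, and peaks that were not called may recur less. Promoter content is argued against by a difference of 24.65 percentage points outside promoters. As a hypothesis, the stage of the cells may set these classes apart. Batches shared by the DN3 libraries, which the labels do not give, and differences in depth between the lists remain open.

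LINE elements, retrotransposons spread over the genome, held 12.6% of the formaldehyde DN3 peaks and 2.75% of the double-fixed DN3 peaks. Weak calls in a list without IDR could be a source, since the LINE share in the lowest-scored of 4 parts was 2.26 times that in the highest (17.5% and 7.77%), and it was 15.6% in peaks absent from the double-fixed list and 5.21% in recurring ones. They are argued against as the whole source, because among the highest-scored peaks outside promoters the LINE share was still 2.2 times that of the double-fixed list (8.22% and 3.74%). The lower promoter content of the formaldehyde list is argued against as well, by a ratio of 3.65 outside promoters. No biological explanation was tested, since both lists come from DN3 cells, and the fixation remains open.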

How the results depend on the processing

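The comparisons of fixation by gene list, the alternatives for the promoter share by fixation, the settings outside promoters and those without the gene with the most stage-specific peaks are tests chosen only after the result was seen. Of 192 alternatives, 150 left a result with its direction and side of the threshold or within its counting error. Another 26 moved a value or count. In 4 a call ended, in 1 a call was made, and in 11 an uncalled gene list turned direction. Gene lists by stage made up 112 of the alternatives and those by fixation 28, mostly for lists that were never called. The 4 overlap shares moved beyond their counting error in 6, 6, 5 and 6 of 7 alternatives each. No paired analysis was possible because the labels share replicate numbers between groups but each group has 1 list with no values per replicate. Tests per replicate, leaving out replicates and motif searches were not run, since the lists hold no values per replicate and no genome sequence was used here. Depth was unknown, so peaks missing from a list for want of reads cannot be counted. DN3-only peaks recurred in the formaldehyde list by 19.8 to 27.93 percentage points more than DN1-only peaks under all 6 alternatives run. The progenitor list kept its call under all 8 alternatives (adjusted permutation p 0.0013 to 0.0104), and the T-lineage list under 7 (0.0013 to 0.026).

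The overlap shares, in the order DN1 in DN3, DN3 in DN1, double-fixed in formaldehyde and formaldehyde in double-fixed, were 64.32%, 51.55%, 25.01% and 25.15% with 50% of both spans, 62.31%, 49.94%, 23.49% and 23.62% with centres within 100 bp, and 69.98%, 55.9%, 33.44% and 32.94% with gaps of up to 500 bp. These rules differ by construction in how close peaks must lie. With both lists cut to the higher-scored of 2 parts the shares were 66.49%, 53.29%, 27.64% and 27.78%. With both cut to the highest of 4 parts they were 61.79%, 49.52%, 28.99% and 29.14%. A peak whose partner was cut counted there as not shared. Against the whole other list, the shares of the highest of 4 parts were 85.0%, 81.3%, 43.0% and 62.3%. With lists of equal length DN1 and DN3 shared 61.52% both ways, and on chromosomes 1 to 19 29.06% of formaldehyde peaks were in the double-fixed list. The promoter share of DN3-only minus DN1-only peaks was 0.07 percentage points with 50% of both spans and 0.42 within 2500 bp of a TSS (1.11 as reported, and the cause was not tested).

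With each gene counted a single time 1 gene list was called by stage instead of 2, as the T-lineage list had 88.46% (adjusted permutation p = 0.219). By fixation 0 lists were called within 50 kb of a TSS, where the cytokine list had 30.67% (adjusted permutation p = 0.148; 1 list had an unadjusted p under 0.01 and 3 under 0.05), and 2 outside promoters, where the NK and innate lymphoid list had 36.51% (adjusted permutation p = 0.0299). Uncalled lists that turned by stage were Notch 48.39%, stromal 33.33% and housekeeping 63.64% in the higher-scored of 2 parts, cytokine 52.0% and housekeeping 46.15% with equal lengths, partner factors 67.65% within 50 kb and B cell 61.54% outside promoters. By fixation they were partner factors 49.57%, B cell 45.83% and later thymocyte 45.57% within 50 kb, and erythroid 56.25% outside promoters. For these changes the cause was not tested.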

Other observations

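The regions, genes and tests in this part were all chosen only after the result was seen, and no test was made of the regions. Over all genes, 63.5% of the stage-specific peaks were DN3-only, the share against which the counts below can be read. The stretch between Bcl11b and the next protein-coding gene, Gm52008 (chromosome 12, 107112137 to 107910402), held 2 DN1 peaks and 22 DN3 peaks, of which 20 were DN3-only and 8 of these were also in the formaldehyde list. The highest-scored of its DN3 peaks lay at 107160106 to 107160376 (score 224.3). An enhancer of Bcl11b is known on this side of the gene. Between Gata3 and Celf2 (chromosome 2, 7396342 to 9857077) there were 2 DN1-only, 8 shared and 19 DN3-only peaks, and 8 of the DN3-only peaks were in the formaldehyde list. Peaks assigned to Gata3 by nearest TSS were 3 in number and DN1-only, so this side of the locus as a whole leaned the other way. Between Myc and Gsdmc (chromosome 15, 61990362 to 63775970), where enhancers of Myc are known, there were 3 DN1-only, 11 shared and 37 DN3-only peaks, including the highest-scored DN3-only peak of the genome (63255720 to 63255990).

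Over the T cell receptor alpha and delta segments (chromosome 14, 52427967 to 54224198) there were 29 DN1-only, 65 shared and 107 DN3-only peaks, and over the T cell receptor beta segments (chromosome 6, 40891296 to 41558371) 9, 15 and 18, which is near the share over all genes. The V segments of the immunoglobulin heavy chain (chromosome 12, 113572929 to 116009954) held 7 DN1-only, 65 shared and 70 DN3-only peaks, of which 13 DN3-only peaks were in the formaldehyde list. V segments are paralogs of each other, and how reads that fit several of them were placed was not examined here. Over all genes, the largest excesses of DN1-only peaks were at Cmip (9 against 1), Plcg2 (9 against 1), Rasgef1b (9 against 1) and Arhgap6 (8 against 0). Those of DN3-only peaks were at Mir6388 (32 against 4) and Mir7094-2 (24 against 3) in the immunoglobulin V region, Dad1 beside the T cell receptor alpha locus (32 against 9) and Gm20740 (19 against 0) in the Myc stretch. None of these passed the exact binomial test after adjustment (0.985 or more).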
